A study of Homo sapiens with 4 samples.

How the data were processed

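The series measured gene expression in SW620, a human colon cancer cell line, on 4 Affymetrix arrays. Per the labels, cells carrying the surface protein CD133 (CD133+) and cells lacking it (CD133-) were separated with magnetic beads, single cells of each kind were grown into clones, and the expanded clone cells were purified by CD133 again before RNA extraction. Each group is 1 clone measured on 2 arrays. Clone and CD133 status cannot be told apart in this design. Nothing in the labels says that the 2 arrays of a clone came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

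The deposited values were log2 probe-set signals, as their range on every array shows, with 1 value per probe set and array. The submitters' processing notes name Affymetrix Expression Console, without a version. The background correction, normalization and summarisation method were not given in the sources used here. The table held 54675 probe sets on each array, of which 62 were Affymetrix controls. All 4 value columns belonged to the 4 samples. The deposited array medians were 4.55 and 4.60 for CD133+ and 4.45 and 4.53 for CD133-, a spread of 0.144. Under a rule fixed before the data were examined, a spread above 0.1 led to quantile normalization of the deposited values, so that all 4 arrays share the same distribution. This step removes any true difference between groups in the overall distribution of signal.

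Probe sets were named through the platform's annotation table. Of the probe sets, 41091 named 1 gene, 1801 named several genes and 11721 other than the controls were not listed there and stayed unnamed. Those naming 1 gene covered 19777 genes, of which 19735 matched the RefSeq human gene table (assembly GRCh38.p14) by gene ID, with 0 symbols changed. That table was used for names, chromosomes and the order of neighbouring genes. A gene was represented by the probe set with the highest mean over the 4 arrays, and where other probe sets of a named gene, dim ones included, had the opposite sign this is stated. The 3956 genes in the lowest 20% of mean level, below a log2 signal of 3.75, were left out, which left 15821 genes.

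The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend of the variance on the mean level. Benjamini-Hochberg adjustment ran over the 15821 genes, and a gene was called changed at an adjusted p under 0.05. With 2 arrays per group an exact two-sided permutation test of a single gene cannot give a p below 0.333, so the calls rest on the variance that limma shares across genes (prior degrees of freedom 6.17). The number of arrays limits the precision: the median standard error of the log2 difference was 0.178 over all genes and 0.134 over the called genes. Errors after ± are standard deviations over the 2 arrays of a group, and differences are CD133+ minus CD133-.

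Before the data were examined, 30 gene lists were written down for colon cell types, stem cell markers, signalling pathways, drug response, stress and contaminating cells. They were tested with camera on the same fit, with a preset correlation between genes of 0.01 and adjustment over the 29 lists with at least 5 measured members. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation camera also uses only the degrees of freedom left by the 4 arrays, so a list can hardly pass there. A call lost in that setting need not come from a larger correlation. Camera was also run for 23 chromosomes with at least 20 measured genes. The rule for named genes, fixed at the same time, took PROM1, the 12 genes with the largest positive and the 12 with the largest negative difference among called genes whose arrays separate the groups, skipping uncharacterised loci, up to 4 members with the smallest p in each list described, and 14 genes always given. Of these last, KRT20 had a probe set below the level filter and was not tested.

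The other alternatives, also fixed in advance, were no level filter, a filter at the median level, eBayes without trend or with robust settings, centring each array on its median, the mean of a gene's probe sets, all probe sets one by one, the replicate number as a block, an adjusted p under 0.01, a test against a 1.5-fold change (treat), and leaving out each array in turn. Leaving out an array leaves a group with 1 array, which is then assumed to vary like the other group. Values as deposited, and a test without the genes of 3 chromosome stretches, were added after seeing the data. A logarithm with an offset was not needed for values already on the log2 scale.

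A search for stretches of neighbouring genes was also added after seeing the data, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. On each chromosome it took the run of at least 20 genes, in steps of 5 genes, whose mean difference (single genes limited to 1.5 in size) lay farthest from the rest of the chromosome, as a z value, and compared it with 1000 permutations of the gene order. It was run in the same way on the difference between the replicate arrays of each clone. It was repeated after removing from each difference its running median over 501 genes ranked by mean level.

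The test was checked on simulated data with 15821 genes, 2 arrays per group and 20 simulations of 200 changed genes. It called 85.0% of the genes changed 2-fold and 38.1% of those changed 1.5-fold, 0 with the wrong sign. Of its calls 8.75% were false, more than the threshold on the adjusted p is meant to allow. At an unadjusted camera p under 0.05, lists shifted by 0.5 on the log2 scale were found in 20 of 20 simulations and unshifted lists were called in 0. The search for stretches found 10 of 10 simulated shifted chromosomes and called 1 unshifted chromosome. The simulated noise was independent between genes, whereas deviations of same-numbered real arrays correlated across genes (r = 0.429). These rates may therefore not hold for the real arrays.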

Results

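Gene expression was measured in clone cells of SW620, a cell line derived from a metastasis of a human colon adenocarcinoma, with 2 arrays of a CD133+ clone and 2 arrays of a CD133- clone. Per the labels, the CD133+ and CD133- populations may differ in tumour formation and in response to anti-cancer drugs. With 1 clone per group, the comparison shows which genes differ between these clones and cannot tell CD133 status from clone. Below, CD133+ and CD133- cells mean the cells of these clones. The deposited log2 signals ran from 2.52 to 14.57 over 54675 probe sets on each array. Over the 15821 genes tested, replicate arrays correlated across genes with r = 0.992 in both clones, and arrays of different clones with r between 0.977 and 0.988. Replicate arrays differed by at least 2-fold in 51 genes for CD133+ and 47 genes for CD133-, against 207 to 729 genes for pairs of arrays from different clones. Pairs with CD133- replicate 1 gave 370 and 729 genes, and pairs with CD133- replicate 2 gave 207 and 218. CD133- replicate 1 also had the highest upper quartile of deposited values (6.91, against 6.61 to 6.71 on the other arrays). The 3' over 5' log2 difference of ACTB, a sign of RNA length, was 0.71 and 1.92 on the CD133+ arrays and 1.18 and 0.92 on the CD133- arrays, so CD133+ replicate 2 stood apart. For GAPDH it was 0.097 and 0.090 against 0.017 and 0.026.

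PROM1, the gene that encodes CD133, was the gene with the largest difference. Its 1 probe set (204304_s_at, on chromosome 4) had a log2 signal of 8.59 ± 0.19 (SD, n = 2) in CD133+ and 3.33 ± 0.029 (SD, n = 2) in CD133- cells. The log2 difference was 5.26 (SE 0.21, 38.3-fold, limma adjusted p = 4.21e-05). The CD133- signal lay below the level of 3.75 under which whole genes were left out, so the fold may understate the change. PROM1 was the sorted antigen, and its difference checks the labels.

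In CD133+ cells 207 genes were higher and 370 were lower than in CD133- cells, 577 in all at a limma adjusted p under 0.05. Of these, 41 were at least 2-fold higher and 136 at least 2-fold lower. The balance depended on the scaling: 35.9% of the called genes were higher after quantile normalization, 21.1% (87 of 413) in the values as deposited and 11.4% (52 of 457) with each array centred on its median. The median difference over all genes was 0.058, 0.028 and -0.051 in these settings. At an unadjusted p under 0.05 there were 3258 genes. The 2 arrays of each clone lay apart from those of the other in 51.6% of genes, where chance gives 33.3%, and in all 577 called genes. The count fell to 124 without CD133- replicate 1 and was 388 without CD133- replicate 2, and a fit without the trend of variance on level called 12.

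After PROM1, the largest positive differences were those of LINC02582 and AGR2. AGR2, a protein disulfide isomerase of mucus-secreting cells, had a log2 signal of 12.11 ± 0.075 (SD, n = 2) in CD133+ and 10.02 ± 0.011 (SD, n = 2) in CD133- cells, a log2 difference of 2.09 (SE 0.082, 4.25-fold, limma adjusted p = 4.21e-05). The non-coding RNA LINC02582 was higher by 2.45 (SE 0.23, limma adjusted p = 0.00815), and CAPN6, a calpain-family protein, by 1.83 (SE 0.20, limma adjusted p = 0.00930) from a CD133- signal of 3.83, close to the lowest level tested. MAD1L1, a spindle checkpoint gene, was higher by 1.71 (SE 0.17), and LCN2, the siderophore-binding lipocalin, by 1.48 (SE 0.22). The other genes of this group were MYH4, a muscle myosin heavy chain, at 1.73, SYNE1, a nuclear envelope spectrin-repeat protein, at 1.67, ZNF32 at 1.52, MYEF2 at 1.52, EEF1A2, a translation elongation factor, 2.84-fold higher, and KLHL29 at 1.45, with limma adjusted p between 0.0110 and 0.0284. The mean over all probe sets of a gene was 0.40 for SYNE1, 0.36 for MYEF2 and 0.43 for KLHL29, none of them past the threshold, and 0.83 for CAPN6, which passed (adjusted p = 0.0346). Without CD133- replicate 1 the adjusted p was 0.0681 for EEF1A2 and 0.0578 for LCN2, and without CD133- replicate 2 it was 0.0538 for MYEF2. For MYEF2, 5 of 6 probe sets had the sign of the brightest, and for SYNE1 3 of 5.

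The largest negative differences were those of NNMT, nicotinamide N-methyltransferase, and CYTL1, a secreted cytokine-like protein. NNMT had a log2 signal of 5.38 ± 0.33 (SD, n = 2) in CD133+ and 8.44 ± 0.0036 (SD, n = 2) in CD133- cells, a difference of -3.06 (SE 0.21, limma adjusted p = 0.00107). CYTL1 had 4.30 ± 0.15 (SD, n = 2) and 7.27 ± 0.053 (SD, n = 2), a difference of -2.97 (SE 0.21, limma adjusted p = 0.00124). The protease inhibitor CSTA, cystatin A, was at -2.03 (SE 0.21), and SERPINB5, maspin, at -1.83 (SE 0.21). SMOC2, a secreted matrix-associated protein, was at -2.17 (SE 0.29) and IGFBP2, a binding protein of insulin-like growth factors, at -2.01 (SE 0.20). The SMOC2 signal in CD133+ cells was 3.91, close to the lowest level tested. The transcription factors RUNX2 and NR2F1 had differences of -1.82 and -1.73. ITPR2, an inositol trisphosphate receptor, was at -2.23, PKIB, an inhibitor of protein kinase A, at -2.05, SHROOM2, an actin-binding protein, at -1.95, and APOBEC3G, a cytidine deaminase, at -1.76. The limma adjusted p of these 10 genes lay between 0.00815 and 0.0125. Of the probe sets for RUNX2, 2 of 6 had the sign of the brightest, for APOBEC3G 1 of 2 and for ITPR2 3 of 4. With the mean over all probe sets neither RUNX2 (-0.096) nor APOBEC3G (-0.63) passed, and NNMT at -1.85, PKIB at -1.27, SERPINB5 at -1.05 and SMOC2 at -1.22 passed with smaller differences.

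**Figure D1:**
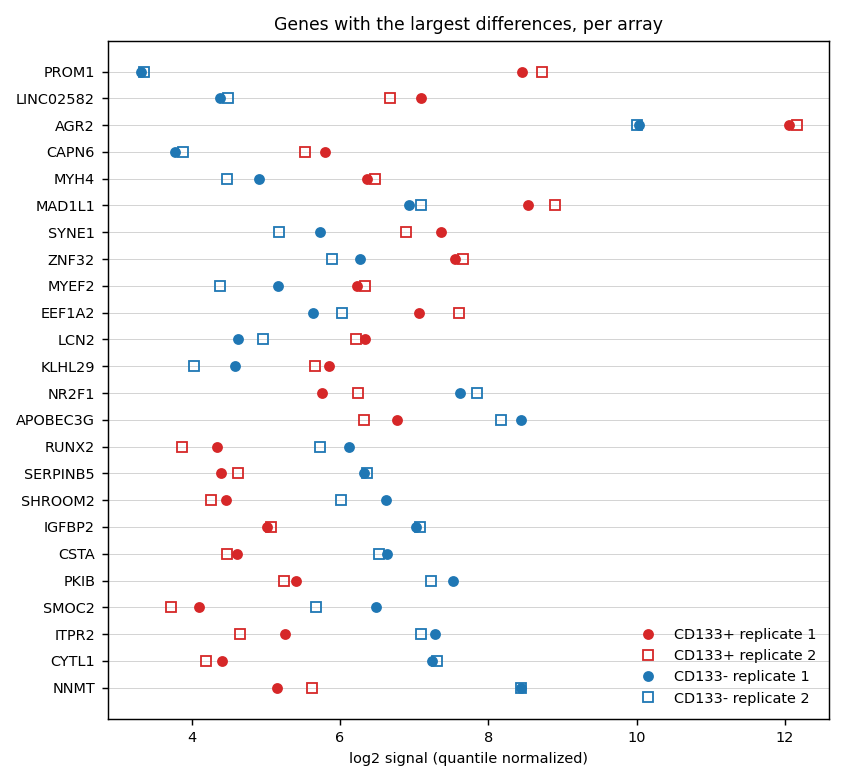
Quantile-normalized log2 signal on each of the 4 arrays (horizontal axis) for PROM1 and the other named genes with the largest differences, ordered by difference; red is CD133+, blue CD133-, filled circles replicate 1 and open squares replicate 2. The arrays of the clones lie apart for every gene shown, as the rule that chose the genes required, and by most for PROM1 (8.59 against 3.33 on average).

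Genes of cholesterol synthesis were lower in CD133+ cells as a list (camera adjusted p = 6.62e-05, median log2 difference -0.28 over 13 measured members). The adjusted p was 0.888 with an estimated correlation. Of the members, 4 fell and 0 rose in limma over all genes, and 5 fell adjusted over the list alone, while 12 of 13 had a negative sign. INSIG1, a regulator of sterol sensing, fell by 0.84 (SE 0.15, limma adjusted p = 0.0246), SQLE, squalene epoxidase, by 0.67 (SE 0.12, adjusted p = 0.0246), DHCR7, the final reductase of the pathway, by 0.64 (SE 0.10, adjusted p = 0.0196) and IDI1, isopentenyl diphosphate isomerase, by 0.57 (SE 0.11, adjusted p = 0.0288). For IDI1, 2 of 4 probe sets had this sign, and for SQLE 3 of 4. With the mean over all probe sets of a gene IDI1 was at -0.28 (adjusted p = 0.315), SQLE at -0.43 (0.189) and INSIG1 at -0.84 (0.0502), and of the 4 only DHCR7 passed. None of these 4 genes passed without CD133- replicate 1, where their limma adjusted p ran from 0.0949 to 0.175, while the list kept an adjusted p of 3.82e-05. Without CD133- replicate 2 it was 0.0523 for INSIG1, 0.0716 for SQLE and 0.107 for IDI1.

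Goblet cell markers, genes of the mucus-secreting cells of the intestine, were higher in CD133+ cells as a list (camera adjusted p = 0.00421, median 0.32 over 14 measured members, adjusted p = 0.888 with an estimated correlation). In limma 3 members rose, 0 fell and 11 did not pass, and adjusted over the list alone 3 rose and 0 fell. AGR2 was 1 of the 3 and lies in the shifted stretch of chromosome 7 described below. The others that rose were TFF1, a trefoil peptide, at 1.38 (SE 0.26, adjusted p = 0.0288) and the membrane mucin MUC13 at 0.97 (SE 0.16, adjusted p = 0.0209). MUC5AC, a secreted mucin, was at 0.70 (SE 0.23, adjusted p = 0.140) and did not pass. MUC13 did not pass in the values as deposited (adjusted p = 0.0720) or with centred arrays (0.111), and without 1 array at a time it had 0.0509 (CD133+ replicate 1) and 0.0912 (CD133- replicate 1). TFF1 had 0.0589 without CD133+ replicate 2 and 0.0662 without CD133- replicate 2.

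Cytokines and chemokines that NF-kappaB induces were lower in CD133+ cells as a list (camera adjusted p = 0.0398, median -0.19 over 15 measured members, adjusted p = 0.890 with an estimated correlation). In limma 5 members fell and 0 rose, 6 adjusted over the list alone, while 7 of 15 had a positive sign. The neutrophil chemokines CXCL2 and CXCL3 fell by 1.33 (SE 0.23, adjusted p = 0.0232) and 1.12 (SE 0.22, adjusted p = 0.0347), IL18 by 0.93 (SE 0.16, adjusted p = 0.0222), CCL20 by 0.72 (SE 0.12, adjusted p = 0.0212) and LIF by 0.47 (SE 0.096, adjusted p = 0.0389). LIF was named after its value was seen. The other 2 probe sets of CXCL2 did not share this sign, and the mean over its probe sets was -0.33 (adjusted p = 0.335). The list lost its call in the values as deposited (adjusted p = 0.0905) and with centred arrays (0.139), and it had 0.264 without CD133+ replicate 2, the array with the largest ACTB 3' over 5' difference, and 0.0541 without CD133- replicate 2. Its median was -0.0067 without CD133+ replicate 2 and -0.40 without CD133+ replicate 1, -0.095 and -0.29 without CD133- replicates 1 and 2, -0.043 with no filter on level and -0.069 with the mean of probe sets. Without CD133- replicate 1 the limma adjusted p was 0.114 for CXCL2, 0.170 for CXCL3, 0.0837 for IL18 and 0.111 for CCL20, and without CD133- replicate 2 it was 0.0699 for both IL18 and CCL20. CXCL3 had 0.0532 without CD133+ replicate 1, 0.0903 without CD133+ replicate 2 and 0.0512 in the values as deposited.

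**Figure D2:**
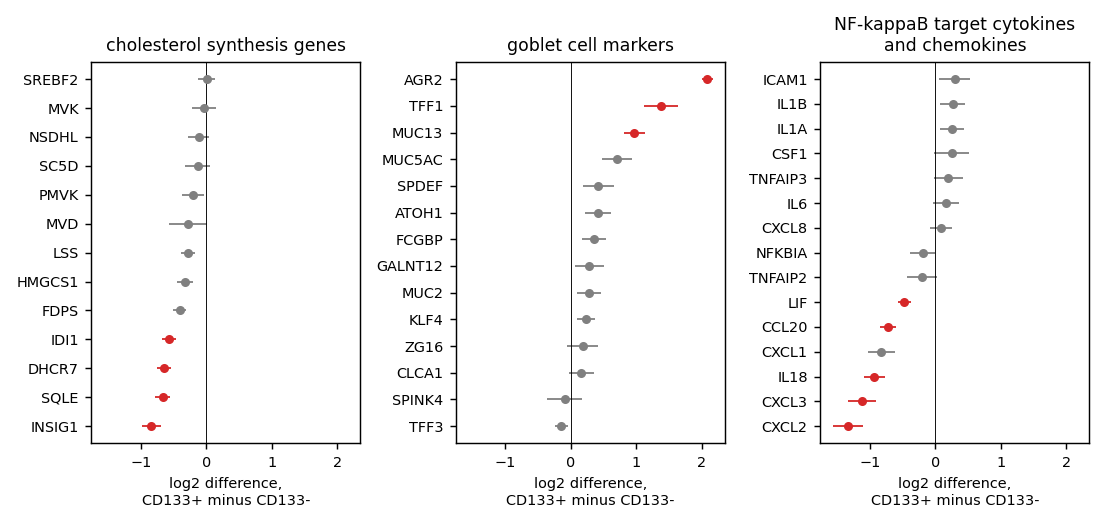
Log2 difference, CD133+ minus CD133- (horizontal axis), of every measured member of the cholesterol synthesis, goblet cell and NF-kappaB cytokine lists; bars are standard errors, and red marks genes with an adjusted p under 0.05. Of the cholesterol genes 12 of 13 lie below 0, while the cytokines lie on both sides.

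Among surface proteins used to mark colon cancer stem cells, CD44, the hyaluronan receptor, was lower in CD133+ cells, with a log2 signal of 6.16 ± 0.11 (SD, n = 2) against 7.37 ± 0.057 (SD, n = 2), a difference of -1.21 (SE 0.18, limma adjusted p = 0.0163). The aldehyde dehydrogenase ALDH1A3 was lower as well, by -1.30 (SE 0.22, limma adjusted p = 0.0222). No other of the 15 measured members passed over all genes, and adjusted over the list alone 2 were higher and 6 lower. ALCAM was at -0.60 (SE 0.17, adjusted p = 0.101), CD24 at -0.43 (SE 0.13, adjusted p = 0.116), EPCAM at -0.26 (SE 0.085, adjusted p = 0.141), ABCG2 at 0.15 (SE 0.15, adjusted p = 0.605) and ALDH1A1 at 0.056 (SE 0.19, adjusted p = 0.893). The list did not pass (camera adjusted p = 0.516), its median being 0.056, its mean -0.15 and the direction of its test downward. With fry it had the lowest adjusted p of all lists tested, 0.0536, which did not pass either. For CD44, 10 of 13 probe sets had the sign of the brightest, and for CD24 5 of 6. The mean of CD44 over all probe sets was -0.59 (adjusted p = 0.114). Its adjusted p was 0.0773 without CD133- replicate 1, and that of ALDH1A3 was 0.0591 without CD133- replicate 2.

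Of the 13 measured intestinal stem cell markers SMOC2 fell and 0 rose, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.680), and LGR5 was at -0.45 (SE 0.24, limma adjusted p = 0.325). Of 17 Wnt target genes, DKK1, a secreted Wnt antagonist, fell by 1.33 (SE 0.18, limma adjusted p = 0.0125) and 3 fell adjusted over the list alone (camera adjusted p = 0.169). DKK1 had an adjusted p of 0.0551 without CD133- replicate 1. The Notch list had 2 of 19 members lower and 0 higher by both counts (camera adjusted p = 0.810). These were HES6, a HES-family transcription factor, at -1.05 (SE 0.12, limma adjusted p = 0.00930) and the ligand JAG1 at -0.35 (SE 0.077, limma adjusted p = 0.0494). JAG1 did not pass in the values as deposited (adjusted p = 0.0562) or with centred arrays (0.0555), nor without CD133+ replicate 2 (0.0844), CD133- replicate 1 (0.306) or CD133- replicate 2 (0.128), nor with the mean of its probe sets (-0.28, adjusted p = 0.228) or no filter on level (0.0510). Hedgehog pathway genes had a median of 0.39, with 11 of 12 positive and no member past the threshold by either count (camera adjusted p = 0.0926). None of 20 TGF-beta and BMP pathway genes passed by either count (camera adjusted p = 0.516).

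Among drug-related genes, ABCB1, the P-glycoprotein efflux pump, was higher in CD133+ cells by 1.32 (SE 0.27, limma adjusted p = 0.0382), the only 1 of 13 ABC transporters to pass, also adjusted over the list alone (camera adjusted p = 0.914). It did not pass in the values as deposited (adjusted p = 0.0760), with centred arrays (0.0727), without CD133+ replicate 1 (0.0946), without CD133- replicate 2 (0.0753), without the genes of the chromosome stretches (0.0587) or with the mean of its probe sets (0.86, adjusted p = 0.0938). TYMS, thymidylate synthase and the target of fluorouracil, was at -0.31 (SE 0.11, limma adjusted p = 0.165), and 0 of 15 fluoropyrimidine and folate genes passed over all genes, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.680). None of 17 DNA repair and topoisomerase genes passed over all genes, with 1 lower adjusted over the list alone (camera adjusted p = 0.680). Of 19 pro-apoptotic genes BIK rose by 0.51 (SE 0.097, limma adjusted p = 0.0325), and of 10 anti-apoptotic genes CFLAR, an inhibitor of caspase activation, fell by 0.88 (SE 0.14, limma adjusted p = 0.0198). Adjusted over the list alone, 2 and 2 of the pro-apoptotic genes and 1 and 2 of the anti-apoptotic genes were higher and lower (camera adjusted p = 0.810 and 0.877). For CFLAR 11 of 14 probe sets had this sign, the mean over all of them was -0.32 (adjusted p = 0.280), and its adjusted p was 0.134 without CD133- replicate 1. BIK, with 1 probe set and an unchanged difference of 0.51, had 0.0645 in the fit to probe-set means, 0.102 with centred arrays, 0.181 without CD133- replicate 1 and 0.0783 without CD133- replicate 2.

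Hypoxia and glycolysis genes moved both ways, with 2 higher and 2 lower of 18 by both counts (camera adjusted p = 0.516). NDRG1 was at 1.35 (SE 0.16, limma adjusted p = 0.00936) and ANKRD37 at 0.72 (SE 0.12, limma adjusted p = 0.0212), against PDK1, a pyruvate dehydrogenase kinase, at -1.54 (SE 0.16, limma adjusted p = 0.00815) and PFKFB3 at -1.10 (SE 0.21, limma adjusted p = 0.0296). Of 16 interferon-stimulated genes 3 rose and 0 fell by both counts, IFITM2 by 0.94, IFITM3 by 0.79 and ISG15 by 0.48 (camera adjusted p = 0.680). IFITM2 and IFITM3 are closely similar genes whose probes may detect both. The immediate early genes FOSB and ATF3 rose by 0.79 and 0.81, 2 of 16 by both counts (camera adjusted p = 0.680). SESN2, a stress-induced sestrin, rose by 0.72, the only 1 of 16 unfolded protein and amino acid stress genes over all genes and 1 of 2 adjusted over the list alone (camera adjusted p = 0.962). Of 24 cell cycle genes CCNB1, cyclin B, fell by 0.51 by both counts (camera adjusted p = 0.444), and MKI67 was at 0.051 (SE 0.11, adjusted p = 0.834), with a sign that turned to -0.030 in the values as deposited and -0.11 with centred arrays. Without CD133- replicate 1 the limma adjusted p was 0.0831 for ANKRD37, 0.0947 for PFKFB3, 0.0810 for IFITM3, 0.278 for ISG15, 0.0811 for SESN2 and 0.167 for CCNB1. Without CD133- replicate 2 it was 0.0687 for ANKRD37, 0.0684 for PFKFB3, 0.0666 for ISG15, 0.0522 for ATF3, 0.0535 for SESN2 and 0.0699 for CCNB1, and without CD133+ replicate 1 it was 0.0872 for PFKFB3. With centred arrays it was 0.163 for ANKRD37, 0.158 for ISG15, 0.113 for SESN2 and 0.0597 for ATF3, and in the values as deposited 0.0846, 0.0524 and 0.0538 for the first 3 of these. With the mean over all probe sets of a gene PDK1 was at -0.77 (adjusted p = 0.0643), ANKRD37 at 0.46 (0.154) and ATF3 at 0.47 (0.266), none of them past the threshold. ISG15, with 1 probe set and an unchanged difference of 0.48, had an adjusted p of 0.0653 in that fit. For ATF3 2 of 3 probe sets had the sign given.

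Of 22 epithelial junction and keratin genes CLDN7, a tight junction claudin, rose by 0.80 (SE 0.14, limma adjusted p = 0.0247), with 3 higher and 1 lower adjusted over the list alone, and CDH1, E-cadherin, was at 0.26 (SE 0.089, adjusted p = 0.149; camera adjusted p = 0.962 for the list). Of 17 mesenchymal genes SNAI2, a repressor of E-cadherin, fell by 0.58 (SE 0.10, limma adjusted p = 0.0249), with 1 higher and 3 lower adjusted over the list alone, and VIM, vimentin, was at 0.24 (SE 0.098, adjusted p = 0.224; camera adjusted p = 0.914 for the list). For CDH1 and VIM 1 of 2 probe sets had the sign given. The integrin subunit ITGAV fell by 0.97 (SE 0.17, limma adjusted p = 0.0231), 1 of 15 integrins over all genes and 1 of 3 adjusted over the list alone (camera adjusted p = 0.962). PLAUR, the urokinase receptor, rose by 0.74 (SE 0.13, limma adjusted p = 0.0224), the only 1 of 16 matrix protease genes over all genes, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.680). EREG, an EGF receptor ligand, fell by 0.60 (SE 0.095, limma adjusted p = 0.0190), 1 of 20 growth factor genes, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.680). Without CD133- replicate 1 the limma adjusted p was 0.165 for CLDN7, 0.0589 for SNAI2, 0.148 for ITGAV, 0.115 for PLAUR and 0.144 for EREG, and without CD133- replicate 2 it was 0.0968 for SNAI2 and 0.0570 for EREG. With the mean over all probe sets of a gene PLAUR was at 0.62 (adjusted p = 0.0681) and EREG at -0.52 (0.0852), and SNAI2, with 1 probe set and an unchanged difference of -0.58, had 0.0511 in that fit. CLDN7 had 0.118 with centred arrays and 0.0562 in the values as deposited.

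No member passed by either count among the enterocyte (15 measured), enteroendocrine (12) and class I antigen presentation (13) lists, with camera adjusted p of 0.877, 0.680 and 0.680. CDX2, an intestinal transcription factor, was at 0.16 (SE 0.20, adjusted p = 0.685) and turned to -0.011 with centred arrays. Markers of cells that a purified line should lack gave the same result: 0 of 10 leukocyte markers (camera adjusted p = 0.877) and 0 of 12 fibroblast and endothelial markers (0.680) passed by either count. Of the cancer-testis genes 4 were measured, too few for the list test, and 0 passed.

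Called genes were concentrated in 3 chromosomal stretches, found by a search chosen after seeing the data. On chromosome 2, 90 of 235 neighbouring genes from HNMT to MREG fell and 0 rose (median -0.50). On chromosome 5, 56 of 155 genes from HMGCS1 to ARSK fell and 0 rose (median -0.50). On chromosome 7, 46 of 235 genes from PRKAR1B-AS1 to MRPS17 rose and 1 fell (median 0.34). The z values were -13.4, -14.5 and 11.1, against at most 8.34 in size between replicate arrays. The permutation p of 0.001 for each is the smallest that 1000 permutations can give. Differences between replicate arrays reached it on many chromosomes as well, among them 2 and 5 in both clones. The stretches held 193 of the 577 called genes and 3.95% of the genes tested, and 384 called genes lay outside them. Among the genes named here, PDK1, CFLAR and ITGAV lie in the stretch of chromosome 2, NR2F1, CCNB1 and HMGCS1 in that of chromosome 5, and AGR2 and MAD1L1 in that of chromosome 7. A fit without the genes of these stretches called 205 genes in limma, all 205 among the 384.

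**Figure D3:**
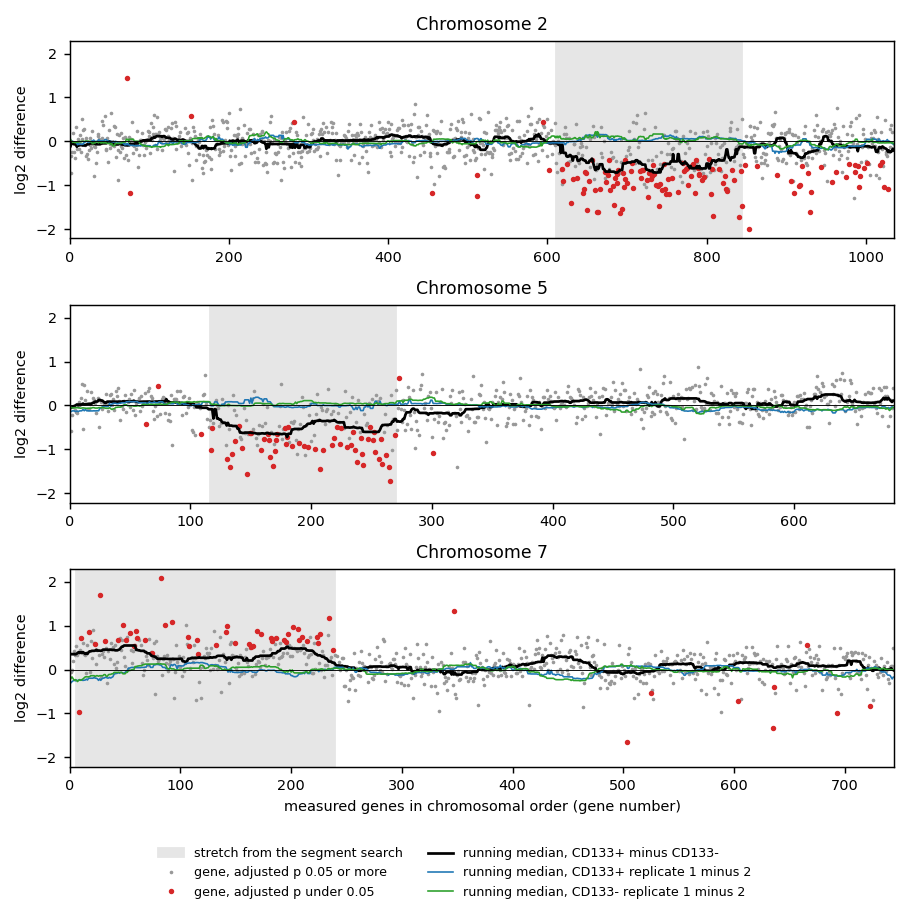
Log2 difference, CD133+ minus CD133- (vertical axis), of measured genes in chromosomal order on chromosomes 2, 5 and 7; red points are genes with an adjusted p under 0.05, the black line is a running median, the blue and green lines are running medians of the difference between replicate arrays of each clone, and the grey bands are the stretches. The black line lies near the medians of -0.50, -0.50 and 0.34 within the bands.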

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

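Probe sets to which the annotation table gave no single gene name enter none of the comparisons by gene. They include probe sets that name several genes, so their signal need not lie outside the named genes. In the limma fit of all probe sets, 4 of them were at least 2-fold higher in CD133+ than in CD133- cells (adjusted p under 0.05). These were 206785_s_at with a log2 difference of 1.77, 1557051_s_at with 1.37, 211458_s_at with 1.20 and 228642_at with 1.17. Of 9436 such probe sets tested, 22 passed, 7 higher and 15 lower, and 9 were at least 2-fold lower, the farthest being 226535_at at -3.04. They were chosen by size after their values were seen, and no explanation was tested.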

How the results depend on the processing

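PROM1 kept its direction and its call in all alternatives, with log2 differences of 5.12 to 5.40 without 1 array at a time, 5.23 in the values as deposited and 5.16 with centred arrays. The count of 577 changed genes was 12 without the variance trend, 247 with the mean of a gene's probe sets, 144 with all probe sets one by one, 50 at an adjusted p under 0.01, 7 against a 1.5-fold change (4 higher, 3 lower) and 205 without the genes of the chromosome stretches (added after seeing the data), and 124 to 706 without 1 array at a time, lowest without CD133- replicate 1. Of the 577, 391 were among the 413 called in the values as deposited and 396 among the 457 called with centred arrays. Without the trend 565 of the 577 lost their call, among them MAD1L1, ITPR2, SMOC2, CD44 and PDK1. The 177 genes changed at least 2-fold became 12 without the trend, 94, 92 and 91 under the probe-set mean, all probe sets and no stretches, and 89 to 255 without 1 array at a time. The cause was not tested. Of the named genes and lists together, 48 lost their call without the trend, 36 with all probe sets one by one, 21 with the mean of probe sets, 10 with centred arrays, 9 as deposited, 27 and 20 without CD133- replicates 1 and 2, and at most 5 in any other alternative. Calls were gained by 65 with the replicate block, 12 and 10 without CD133+ replicates 1 and 2 and by at most 5 in any other alternative.

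For the cholesterol, goblet cell and NF-kappaB lists the estimated correlations were -0.068, -0.0066 and -0.061, below the preset 0.01. For the Hedgehog list, which was not called, the estimate was 0.299, above the preset (camera adjusted p = 0.942 with it). Tests of the Hedgehog list with the preset may therefore give too small a p. The number of shifted lists, 3, was 0 with an estimated correlation (1 list at an unadjusted p under 0.05, lowest adjusted p 0.888) and 0 with fry (4 lists, lowest adjusted p 0.0536). Without 1 array at a time it was 2 to 4. The number of shifted chromosomes, 7, was 0 with an estimated correlation (3 at an unadjusted p under 0.05, lowest adjusted p 0.156) and 3 to 9 without 1 array at a time, with 3 both without CD133+ replicate 2 and without CD133- replicate 1. The Hedgehog list passed in 5 alternatives, with adjusted p from 0.0113 to 0.0469. The Wnt target list passed in 2 (0.0262 and 0.0370). The NF-kappaB cytokine list also lost its call with all probe sets (0.0539) and with the replicate block (0.0636).

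Signs turned only for genes that did not pass. CDX2 was at -0.011 and MKI67 at -0.11 with centred arrays, MKI67 at -0.030 and CTAG2 at 0.013 in the values as deposited, and MCL1 at -0.015, DNAJC3 at -0.043 and CTAG2 at 0.19 with the mean of probe sets. Of the probe sets of these 3 genes, 2 of 6, 2 of 4 and 1 of 2 had the sign of the brightest, and 2 of 3 for COL1A2. Without 1 array at a time the ranges were -0.019 to 0.12 for MKI67, -0.20 to 0.066 for CTAG2, -0.012 to 0.54 for COL1A2, -0.0065 to 0.27 for MAGEC2, -0.23 to 0.055 for PRAME and -0.14 to 0.25 for ALDH1A1. The cause was not tested. For the 24 lists not past an unadjusted p of 0.05, 50 of 381 alternative fits had a median of the other sign and 0 passed.

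With the replicate number as a block (replicate block) limma called 3030 genes, 1566 higher and 1464 lower (51.7% higher), and of the 213 genes changed at least 2-fold 48 were higher and 165 lower (22.5% higher). The shared numbers have only 2 pairs and the labels do not say that they mark a shared day or culture. Deviations of same-numbered arrays from their group means correlated with r = 0.429 across genes. Signal over background limits the dimmest genes, such as PROM1 in CD133- cells.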

Other observations

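LAMB3, a subunit of an epithelial laminin, was higher in CD133+ cells by 1.40 on the log2 scale (12.30 ± 0.069 against 10.90 ± 0.0021, SD, n = 2, limma adjusted p = 0.000347), and LAMB1, another laminin subunit, was at -1.66 (limma adjusted p = 0.00880). WNT11, a secreted Wnt ligand, was at -1.26 and CEMIP, a hyaluronan-binding protein, at -0.84. KRT16 was at -1.67. PRSS2, a trypsinogen, was at -1.33 (limma adjusted p = 0.000422), but its probes can also detect other trypsinogen genes. These genes were chosen after their values were seen.

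By chromosome, 7 of 23 were shifted in camera with the preset correlation. Chromosomes 2 (adjusted p = 6.42e-07), 5 (0.00459) and 4 (0.0415) were lower in CD133+ cells, and chromosomes 7 (0.00459), 19 (0.0145), 22 (0.0145) and 17 (0.0175) were higher. With an estimated correlation 0 passed. The estimates for chromosomes 2, 5 and 7 (0.0013, 0.0018 and 0.0034) lay below the preset 0.01. Those for chromosomes 4, 17, 19 and 22 (0.013, 0.067, 0.178 and 0.176) lay above it. Of the tests below, the search for stretches, the removal of the trend on level and both comparisons with the difference between replicate arrays were chosen only after the result was seen.

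The stretches of chromosomes 2, 5 and 7 hold 193 of the 577 called genes. A technical difference that varies from array to array predicts a like shift between replicates. The largest median shift between replicates was 0.2036 of that between clones, in stretches chosen by the difference between clones. The search itself gave a z of at most 8.34 in size between replicates against 11.1 or more. These values argue against an array-to-array difference as the whole cause, but not as a part. A technical difference shared by both arrays of a clone would leave the replicates alike, so these comparisons cannot speak to it. On chromosome 2 the search between replicates picked nearly the same genes, HNMT to RPE for CD133+ and MGAT5 to IKZF2 for CD133- (z 5.54 and 5.55). On chromosome 5 it gave a z of 5.19 and 5.41. Removing the trend of each difference on signal level tested an effect of level on the normalization. It moved other chromosomes, such as 14 (z from -6.66 to -6.06), but left the 3 at -13.28, -14.49 and 11.05. The smallest was 1.346 times the largest between replicates. A removal that moves z so little decides little, and its rule was loosened after the result was seen. As first written, the rule would have left the question open. The trend between clones ran from -0.013 to 0.21, short of the stretch medians of -0.50, -0.50 and 0.34. This argues against a smooth trend on level as the whole cause. A copy number difference between the clones stays open: at least 94.87% of the brighter genes of each stretch had its sign (medians -0.64, -0.51 and 0.48, against -0.11, -0.46 and 0.23 in the dimmer genes), but the stretches were chosen by this difference, so a high share follows from the choice and decides nothing. Copy number was not measured here, GC content was not tested, and with 1 clone per group the shifts cannot be tied to CD133 status or to the choice of clone.

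The genes of chromosomes 19 and 22 were higher in CD133+ arrays by 0.096 relative to all genes. Replicate arrays differed by 0.073 and 0.090 for the same 1546 genes, and the smaller of these is 0.7607 of the difference between clones, which is consistent with a technical difference between arrays. A copy number difference cannot be told apart from it, because the nearest arrays of the clones lay only 0.01422 apart, less than the replicates did.

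The lower cholesterol synthesis genes do not rest on the chromosome stretches: without the 1 member lying in them the list median was -0.2801 over 12 genes. The list median stayed negative in each scaling, at -0.28 after quantile normalization, -0.3737 in the values as deposited and -0.4525 with centred arrays. Its size thus depended on the scaling. The median over all genes was also lower in the latter settings (0.028 and -0.051, against 0.058). These settings could therefore hardly bring the list nearer to 0, and they do not decide whether scaling contributes. The list did not pass with an estimated correlation (adjusted p = 0.888) or with fry (0.0546), and the cause of its difference was not tested.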
